A study of Mus musculus with 78 samples.

How the data were processed

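RNA sequencing was done on cerebral arteries of male C57Bl6 mice, and 78 libraries were used. Per the labels' protocols, mice ate freely (ad libitum, AL) or fasted intermittently (IF) for 3 months before surgery. They then had bilateral carotid artery stenosis (BCAS), which narrows both common carotid arteries and chronically lowers blood flow to the brain, or a sham operation. The group labels gave collection at 1, 7, 14, 21 or 30 days after surgery, which made 20 groups of surgery, diet and day. The series design text counted 4 time points and the treatment text left out day 7, so day 7 rests on the group labels alone. Each group had 4 libraries, except BCAS AL on day 1 and sham IF on day 7, which had 3. The fasting schedule and the time of day of collection were not given in the sources used here. No replicate numbers were shared between groups in the labels, so no samples were paired. The libraries had separate titles, and nothing else said that they came from separate animals, so p-values measured only the spread between these libraries.

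Per the labels' protocols, RNA was extracted with an RNeasy kit, and Novogene built the libraries from 2 ug of total RNA. The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to sequencing depth) for 54532 genes, per the file headers, with a gene length in bases that the authors listed for each gene. DESeq 1.10.1 was named, without a role, in the submitters' processing notes. The aligner, the counter, the genome build and the annotation release were not given in the sources used here. Of the gene identifiers, 54409 were in GENCODE M21, and 98.3% of these had the same coordinates there, so positions are given on GRCm38.

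In each library, FPKM multiplied by gene length was a whole multiple of 1 step, within a tolerance of 0.05, for 100% of values under 1000 fragments. This step gave the depth, which ran from 14601572 to 25944175 fragments per library. The mean depth was 18.7 M ± 2.9 M fragments (SD, n = 20) in sham AL, 20.1 M ± 3.1 M (n = 19) in sham IF, 19.4 M ± 2.8 M (n = 19) in BCAS AL and 20.0 M ± 2.4 M (n = 20) in BCAS IF. For a gene of 1 kb, 1 FPKM stood for 15.1 to 26.8 fragments. The totals also carried a factor of 0.938 to 1.119 per library that no header named. Between 12586 and 13449 genes had at least 1 FPKM. Ptgds alone took 5.01% to 10.24% of fragments, and mitochondrial genes took 4.62% to 7.54%. No 2 libraries held identical values.

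FPKM values are not counts, so tests were run on log2(FPKM + 1) with limma 3.58.1 (trend and robust options, statmod 1.5.0, R 4.3.3). This scale understates the change of genes with low values. Genes with at least 1 FPKM in at least 3 libraries were kept, which left 15707. All 78 libraries entered 1 model with a mean for each of the 20 groups, so that the groups shared 1 estimate of the spread. The contrasts were BCAS against sham under each diet and IF against AL after each surgery, on each day and as the mean of the 5 daily differences. Further contrasts were the interaction of BCAS and diet, and F tests of whether the BCAS effect differed between days. P-values were two-sided, adjusted by the Benjamini-Hochberg method over all genes of a contrast, and compared with a threshold of 0.05. Some counts of genes at an unadjusted p under 0.05 are also given. Chance alone gives a share of about 0.05 of the 15707 genes there, so such counts do not by themselves show an effect. Errors of log2 changes are standard errors from that model.

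Gene lists for the cell types that an artery sample can hold and for vascular, stress and metabolic functions were fixed before the data were examined. Of 47 lists, 45 had at least 3 measured members and were tested with camera at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. For each list the members past the threshold were counted among all genes tested and also adjusted over the list alone.

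Named genes followed a rule fixed at the same time and limited to protein-coding genes. For the mean over days it took the 10 largest rises and 10 largest falls past the threshold with the same sign on all 5 days and a mean of at least 1 FPKM in either arm. For single days it took the 5 largest in each direction past the threshold with no overlap between the libraries of both groups and at least 1 FPKM in either group. It also took up to 4 members per list with the smallest p, the 5 smallest p-values of each F test, the 2 smallest where no gene passed, and a fixed panel of vascular, clock, metabolic and marker genes. Other genes are named as chosen after their values were seen.

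The steps were tested on simulated data made from the mean and the fitted spread of each gene, with 100 genes changed by each of 0.5 and 1 on the log2 scale among the 15707. For the mean fasting effect in sham, 96% and 98% were recovered with 8 false calls, and for BCAS under AL on day 7, 56% and 92% with 7 false calls. For the by-day F test under AL, 46% and 84% were recovered with 10 false calls. The simulated genes varied independently, with the same spread in all groups, and no simulated library stood apart. The false calls therefore do not give the error on real libraries where this did not hold, such as those of day 7.

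The alternatives fixed with the design were no filter, a pseudocount of 0.1 FPKM, median-ratio scaling of the libraries, a brain tissue score as a covariate, a fit of only the compared groups, and each library left out in turn. The score was the mean z-score of neuron, astrocyte and oligodendrocyte markers. Added later were limma-voom on the fragments recovered from the steps, a fit without 3 libraries rich in fragments of genes under 300 bases, a clock score as a covariate, and fits of only the compared groups without genes whose variance there was near 0. The clock score was the mean z-score of Dbp, Tef, Hlf, Per1, Per2, Per3, Nr1d1, Nr1d2, Ciart and Bhlhe41 minus that of Arntl, Clock, Npas2 and Nfil3. Each count was also computed for other splits of the same libraries, all 35 on single days and 100 drawn within days for means. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Some genes that the naming rule takes are not reported here.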

Results

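Cerebral arteries were collected from mice that had eaten freely (AL) or fasted intermittently (IF) and then had carotid stenosis (BCAS) or a sham operation, on 5 days after surgery. The 78 libraries comprised 20 of sham AL, 19 of sham IF, 19 of BCAS AL and 20 of BCAS IF, with 3 or 4 libraries per group and day. Depth lay between 14601572 and 25944175 fragments per library. Smooth muscle genes were among the most abundant, with Acta2 at 5170 FPKM ± 1240 (SD, n = 20) and Myh11 at 403 FPKM in sham AL. The 3 libraries richest in fragments of genes under 300 bases held 0.279% (BCAS AL day 1 replicate 2), 0.282% and 0.322% (sham AL day 7 replicates 2 and 4) of their fragments there, against 0.056% to 0.106% in the others.

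The labels give a sham group for each BCAS group, so the effect of carotid stenosis was measured within each diet, first as the mean over the 5 days. Under AL, BCAS raised Ptp4a3, which encodes a phosphatase expressed in endothelium, from 17.2 ± 2.68 FPKM (SD, n = 20) to 27.4 ± 5.65 FPKM (n = 19), a log2 change of 0.63 ± 0.06 (SE) or 1.54-fold (adjusted p = 1.96e-10). Crispld2, which encodes a secreted protein, rose by 0.47 ± 0.05 from 74.5 ± 6.13 to 105 ± 18.7 FPKM (adjusted p = 2.45e-08). Pi15 rose by 0.56 ± 0.09 and the matricellular gene Wisp2 by 0.67 ± 0.11. Falls were led by 2210407C18Rik, which fell by 0.83 ± 0.13 from 3.97 ± 1.46 to 1.83 ± 1.05 FPKM, and by Baiap2l2 and Cck, which fell by 0.65 ± 0.09 and 0.62 ± 0.12. On GRCm38, Ptp4a3 (ENSMUSG00000059895) lies on chromosome 15 at 73723145 to 73758766 and Crispld2 (ENSMUSG00000031825) on chromosome 8 at 119992438 to 120052793. Pi15 lies on chromosome 1 at 17601901 to 17630939, and 2210407C18Rik (ENSMUSG00000037145) on chromosome 11 at 58608204 to 58616075. In all, 155 of 15707 genes passed, 129 higher and 26 lower, and 7 rises and 3 falls exceeded 1.5-fold.

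Further rises under AL were those of Gm37419 (0.91 ± 0.20), Klk10, Nrm, Cd24a and the potassium channel gene Kcnk3 (0.39 ± 0.09). The other named falls were Fbxl22, Plk5, Cnnm2, Myl6b, Mitf, Bag4 and Ttc7b, between -0.44 and -0.15. Of 15 endothelial genes 5 rose, none fell and 10 did not pass (7 rose adjusted over the list alone). The rises were those of the junction genes Cldn5 (0.25 ± 0.07), Esam (0.23 ± 0.05) and Pecam1 (0.25 ± 0.06), and of Egfl7 (0.26 ± 0.06) and Robo4 (0.20 ± 0.05). The median change of this list was 0.12 and its camera adjusted p was 8.49e-06, or adjusted p = 0.459 with an estimated correlation. None of 10 arterial endothelial genes passed over all genes tested and 6 rose adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.000171, or adjusted p = 0.459 with an estimated correlation). Vegfc (0.27 ± 0.08, adjusted p = 0.0653) and Dll4 (0.21 ± 0.06, adjusted p = 0.0957) were the examples closest to the threshold. Of 19 barrier genes 2 rose, the junction gene F11r (0.17 ± 0.04) and the caveolar gene Cav1 (0.17 ± 0.03), and 5 did so adjusted over the list alone (camera adjusted p = 0.0214, or adjusted p = 0.606 with an estimated correlation). Angpt2 (0.25 ± 0.04) and Pgf (0.22 ± 0.05) were the 2 of 17 angiogenesis genes that rose, with 4 rises and 1 fall adjusted over the list alone. Of 19 vasoactive genes 2 rose, the calcium channel gene Cacna1c (0.18 ± 0.04) and the endothelin receptor gene Ednra (0.16 ± 0.04), and 4 rose adjusted over the list alone.

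Single members also rose in the pericyte list (Notch3, 0.28 ± 0.07), the basement membrane list (Col4a1, 0.20 ± 0.05), the protease list (Adamts5, 0.26 ± 0.06), the hypoxia list (Ndrg1, 0.21 ± 0.03, adjusted p = 5.4e-07), the astrocyte list (Fgfr3, 0.20 ± 0.05) and the FoxO list (Txnip, 0.21 ± 0.05). Of 21 cholesterol synthesis genes 2 fell, Srebf2 (-0.13 ± 0.03) and Lss (-0.11 ± 0.03), over all genes and adjusted over the list alone (camera adjusted p = 0.000229, or adjusted p = 0.606 with an estimated correlation). Of 20 clock genes Hlf fell (-0.20 ± 0.05), and 2 fell adjusted over the list alone (camera adjusted p = 0.0199, or adjusted p = 0.459 with an estimated correlation). No member passed in the ribosomal, red blood cell and oligodendrocyte lists, whose medians were 0.07, 0.73 and -0.23 (camera adjusted p = 1.48e-09, 0.0199 and 0.0214, or adjusted p = 0.988, 0.931 and 0.931 with an estimated correlation). Of the panel, Acta2 (0.04, adjusted p = 0.887), Myh11 (0.05, adjusted p = 0.852), Nos3 (0.13 ± 0.06, adjusted p = 0.434), Vegfa (-0.16 ± 0.06, adjusted p = 0.197) and Icam1 (-0.10, adjusted p = 0.744) did not pass, and neither did Edn1, Hif1a, Mmp2, Mmp9, Il1b or Vcam1.

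Without BCAS AL day 1 replicate 3 the count under AL was 86, and without a filter on low values it was 103. The calls of Cldn5, Ednra, Lss, Hlf and Fgfr3 were each lost when any 1 of 8 to 25 single libraries was left out, as were those of Mitf, Myl6b, Plk5 and Ttc7b for 9 to 18 libraries. Bag4 lost its call without BCAS AL day 1 replicate 3. Pecam1, Robo4, Notch3 and Adamts5 lost theirs without 1 of 2 or 3 libraries each, which were BCAS AL day 1 replicates 2 and 3, BCAS AL day 14 replicate 1, BCAS AL day 21 replicate 4, sham AL day 14 replicate 4 and sham AL day 21 replicate 4.

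**Figure D1:**
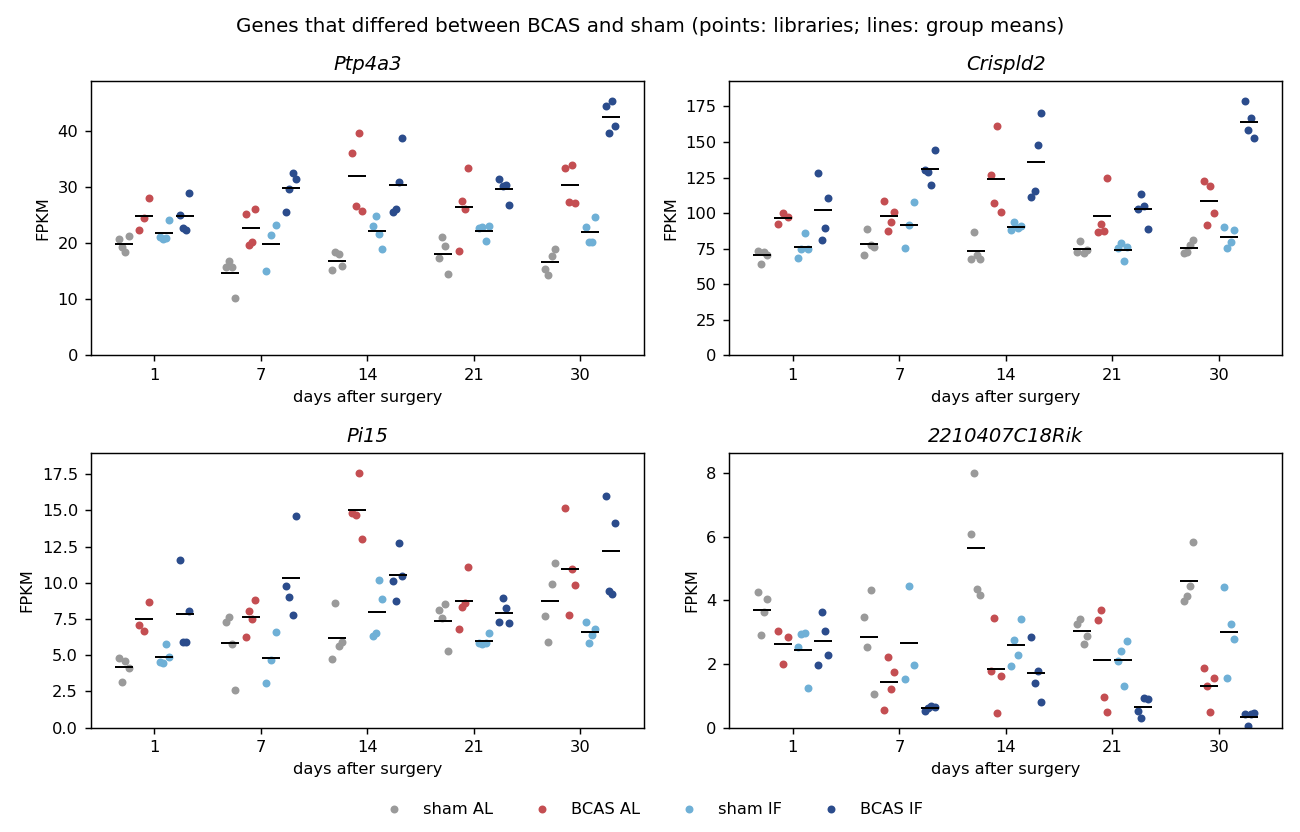
FPKM of Ptp4a3, Crispld2, Pi15 and 2210407C18Rik in each of the 78 libraries (points), by surgery, diet and day after surgery, with lines for group means. Crispld2 had a mean of 105 FPKM in BCAS AL and 127 FPKM in BCAS IF against 74.5 and 82.8 FPKM in the sham arms.

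Day by day under AL, the genes that passed differed. On day 1 the hemoglobin genes Hba-a2 (4.20 ± 0.89), Hbb-bs (3.98 ± 0.95), Hba-a1 (3.88 ± 0.94) and Hbb-bt (3.46 ± 0.85) and the heme synthesis gene Alas2 (1.69 ± 0.38) rose with BCAS. All 5 red blood cell genes rose, over all genes and adjusted over the list alone (camera adjusted p = 7.13e-11, or adjusted p = 0.0425 with an estimated correlation). Hba-a1 was at 385 ± 288 FPKM (n = 3) in BCAS AL and 22.8 ± 11.9 FPKM (n = 4) in sham AL. The α-globin genes and the β-globin genes are near-identical copies, so their separate values are uncertain. The mean log2(FPKM + 1) of the red blood cell list was 4.85 to 7.19 in BCAS AL and 2.14 to 3.06 in sham AL on day 1. It also reached 5.89 in sham AL day 21 replicate 1 and 7.57 in BCAS IF day 21 replicate 4. The amount of blood left in the samples was not measured, so it cannot be told apart from a response to BCAS. Of 20 clock genes Dbp (-1.40 ± 0.28), Per3 (-0.72 ± 0.13) and Tef (-0.52 ± 0.13) fell on day 1, with 4 rises and 8 falls adjusted over the list alone (camera adjusted p = 0.0031, or adjusted p = 0.174 with an estimated correlation). The clock score was -0.03 ± 0.62 (SD, n = 4) in sham AL and -1.83 ± 0.39 (n = 3) in BCAS AL on day 1. On the other days it was between -2.41 and -1.51 in sham AL and between -2.54 and -1.12 in BCAS AL, so the sham group of day 1 stood apart. Kap fell by 1.69 ± 0.30, Fabp3 by 0.71 ± 0.16 and Lyplal1 by 0.63 ± 0.15. None of 14 protease and inhibitor genes passed, and 4 rose adjusted over the list alone (median 0.22, camera adjusted p = 0.00326, or adjusted p = 0.0425 with an estimated correlation). In total 59 genes passed, 35 higher and 24 lower, and 28 passed without the 3 libraries rich in fragments of short genes and 240 without a filter on low values. Leaving out single libraries gave 1 gene without BCAS replicate 3, 23 without BCAS replicate 2, 4 without sham replicate 1, and 26 without sham replicate 2 or 4. Each of the 5 red blood cell calls was lost without sham replicate 1, BCAS replicate 2 or BCAS replicate 3 and without further sham libraries, and those of the other genes named for day 1 without BCAS replicate 3. For Dbp, Tef, Fabp3 and Lyplal1 further single libraries also ended the call, sham replicate 2 in the case of Dbp.

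On day 7, which the group labels gave and the treatment text left out, 413 genes passed under AL, 258 higher and 155 lower. Of 35 splits of the same libraries, 6 with the real one gave as many genes, and the highest other gave 2159. Chance could therefore not be excluded for this number. Leap2 (0.94 ± 0.26), Klk10 (0.93 ± 0.22), Bcl2a1d (0.89 ± 0.25), the linker histone gene H1fx (0.88 ± 0.15) and Pebp4 (0.84 ± 0.21) rose. Gm10800 (-4.51 ± 0.92), the mitochondrial leucyl-tRNA synthetase gene Lars2 (-2.62 ± 0.36, adjusted p = 2.84e-06), Sez6l2, Hapln2 and Rph3a fell. Of 78 ribosomal protein genes 14 rose and none fell (61 rose adjusted over the list alone), among them Rps13 (0.59 ± 0.13), with a median of 0.32 (camera adjusted p = 2.33e-27, or adjusted p = 0.569 with an estimated correlation). Of 71 nuclear-encoded genes of oxidative phosphorylation 6 rose (41 adjusted over the list alone), such as Ndufv3 (0.47 ± 0.11) and Cox5b (0.49 ± 0.13), with a median of 0.27 (camera adjusted p = 2.13e-17, or adjusted p = 0.624 with an estimated correlation). Sham AL replicate 4, whose median correlation with the other libraries was the lowest of the 78 (0.9391), had a mean log2(FPKM + 1) of 6.93 for the ribosomal and 5.83 for the oxidative phosphorylation list. The other sham AL libraries were at 7.28 to 7.83 and 6.25 to 6.68. Those of BCAS AL were at 7.47 to 7.88 and 6.30 to 6.64. The complement genes C1qc (0.44 ± 0.13) and C1qa (0.43 ± 0.12) rose, 2 of 11 and 6 adjusted over the list alone (camera adjusted p = 0.00213, or adjusted p = 0.569 with an estimated correlation). The neurofilament genes Nefm (-0.64 ± 0.17) and Nefl (-0.95 ± 0.27) fell, 2 of 10 neuronal genes and 6 adjusted over the list alone (camera adjusted p = 0.000261, or adjusted p = 0.569 with an estimated correlation). The brain tissue score of the same libraries was 0.94 ± 1.06 (SD, n = 4) in sham AL and -0.14 ± 0.27 (n = 4) in BCAS AL, and 185 genes passed with this score as a covariate. Of the 413 genes 98.3% kept at least 50% of their change in that fit, and the median size went from 0.37 (median SE 0.096) to 0.34 (0.101). The balance of rises and falls turned without the short-gene-rich libraries, among them sham AL replicates 2 and 4, where 72 genes passed, 19 higher and 53 lower. It also turned without a filter on low values, where 551 passed, 222 higher and 329 lower. Leaving out single libraries gave 1750 genes without sham replicate 1, 67 without sham replicate 4, and 660, 45, 200 and 91 without BCAS replicates 1, 2, 3 and 4. The calls of H1fx and Lars2 held without any 1 library, which each time kept sham AL replicate 2 or 4. Lars2 was also lower with fasting against the same sham AL group, so a high value there cannot be told apart from a fall with BCAS. Gm10800 lost its call without sham replicate 4, and the other genes named for day 7 lost theirs without BCAS replicate 2 and, except Rph3a, without at least 1 further library.

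On day 14 under AL 53 genes passed, 44 higher and 9 lower. Pi15 (1.17 ± 0.21), Bcl6b (1.07 ± 0.23), the metalloprotease gene Adamts1 (0.97 ± 0.22), Egfl8 (0.89 ± 0.19), Ptp4a3 (0.86 ± 0.14) and the heat shock cochaperone gene Dnajb1 (0.81 ± 0.17) rose. Transcripts of 2210407C18Rik, the neuropeptide gene Calca (-0.79 ± 0.16), Xdh, Nt5e, Smad6 (-0.46 ± 0.11) and Nr1d2 (-0.57 ± 0.14) fell. The count was 10 without sham replicate 1, 140 without sham replicate 2, 20 without sham replicate 3, and 14 and 23 without BCAS replicates 1 and 3. The calls of Pi15 and Ptp4a3 held without any 1 library, and the others named for day 14 were lost without sham replicate 1 or BCAS replicate 1. On day 21 no gene passed in limma, 1028 had an unadjusted p under 0.05, and limma-voom also called 0, but limma without a filter on low values called 6. Without sham replicate 3 on day 21 1 gene passed. The smallest p-values were those of Epc1 (0.32 ± 0.06, adjusted p = 0.0955) and Fgfr3 (0.47 ± 0.11, adjusted p = 0.462). On day 30 56 genes passed, 14 higher and 42 lower. Ptp4a3 (0.84 ± 0.14), Crispld2 (0.50 ± 0.12), Kcnn4, Clstn2 and Slc11a1 rose, and Nr4a3 (-1.35 ± 0.32), 2210407C18Rik (-1.31 ± 0.28), Jun (-0.98 ± 0.23) and Tnfrsf12a fell. Of 15 heat shock chaperone genes 5 fell, including Dnajb1 (-1.06 ± 0.17), Dnaja1 (-0.87 ± 0.17), Hspa1a (-1.58 ± 0.35) and Bag3 (-0.44 ± 0.09), and 7 fell adjusted over the list alone (camera adjusted p = 5.2e-13, or adjusted p = 0.153 with an estimated correlation). The day 30 count was 7 and 34 without sham replicates 1 and 3, and 30, 23 and 27 without BCAS replicates 2, 3 and 4. The calls of Ptp4a3 and Dnajb1 held without any 1 library, and the others named for day 30 were lost without sham replicate 1. In limma fits of only the compared groups, no gene passed on days 1, 7 and 14 (1576, 1175 and 1885 at an unadjusted p under 0.05) and 5 passed on day 30. Without genes of near-zero variance 1 passed on day 1 in such a fit.

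Under IF, BCAS raised Crispld2 by 0.58 ± 0.05 or 1.5-fold (adjusted p = 2.44e-11), from 82.8 ± 10.2 FPKM (n = 19) to 127 ± 28.5 FPKM (n = 20), as the mean over the 5 days. Ptp4a3 rose by 0.50 ± 0.06 from 21.7 ± 2.3 to 31.4 ± 6.87 FPKM (adjusted p = 2.58e-07), and Pi15 and Wisp2 rose by 0.60 ± 0.09 and 0.60 ± 0.11. Apold1, an immediate early gene of endothelium, rose by 0.51 ± 0.12, Adamts1 by 0.43 ± 0.10, Cyp4b1 by 0.41 ± 0.08 and Fmo2 and the ceramidase gene Acer2 by 0.36. Baiap2l2 (-0.48 ± 0.09), Fbxl22 (-0.47 ± 0.10), Wtip, Tceal6, Grip2, Susd5, Gfra2, Uba2, Dact3 and Acss1 fell. In all 119 genes passed, 82 higher and 37 lower, and 2 rises and 1 fall exceeded 1.5-fold. The endothelial genes Vwf (0.20 ± 0.05) and Pecam1 (0.23 ± 0.06) rose, 2 of 15 and 6 adjusted over the list alone, with a median of 0.08 (camera adjusted p = 0.000191, or adjusted p = 0.449 with an estimated correlation). Angpt2 (0.19 ± 0.04), Pgf (0.26 ± 0.05) and Adamts1 were the 3 of 17 angiogenesis genes that rose, with 4 rises and 1 fall adjusted over the list alone. Of 15 TGF-β genes 3 fell, the inhibitors of this pathway Smad7 (-0.23 ± 0.05), Smad6 (-0.22 ± 0.05) and Skil (-0.16 ± 0.04), with 2 rises and 4 falls adjusted over the list alone.

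Single members rose under IF in the vasoactive list (Cacna1c, 0.21 ± 0.04), the hypoxia list (Ndrg1, 0.14 ± 0.03), the barrier list (Cav1, 0.13 ± 0.03), the immediate early list (Myc, 0.26 ± 0.06), the basement membrane list (Col4a1, 0.18 ± 0.05; camera adjusted p = 0.0493, or adjusted p = 0.731 with an estimated correlation) and the FoxO list (Txnip, 0.19 ± 0.05; camera adjusted p = 0.0395, or adjusted p = 0.449 with an estimated correlation). No member passed in the arterial endothelial list (median 0.12), the heat shock list (-0.05) and the 4 measured cell cycle genes (0.13), for which the camera adjusted p was 0.0493, 0.0395 and 0.00766, or adjusted p = 0.731, 0.737 and 0.0629 with an estimated correlation. Adjusted over the list alone, these lists had 3 rises and 1 fall, 1 fall, and 2 rises. Of the panel, Acta2 (-0.07, adjusted p = 0.88), Myh11 (0.06, adjusted p = 0.897), Vegfa (-0.12, adjusted p = 0.465) and Cldn5 (0.07 ± 0.07, adjusted p = 0.809) did not pass, nor did Nos3, Edn1, Hif1a, Mmp2, Mmp9, Il1b, Icam1 or Vcam1. The count under IF was 77 without BCAS IF day 1 replicate 1 or BCAS IF day 14 replicate 4, and 74 without a filter on low values. The calls of Susd5, Pecam1, Dact3, Cav1, Skil, Vwf, Fmo2 and Col4a1 were lost when any 1 of 6 to 28 single libraries was left out. Those of Txnip, Acss1 and Apold1 were lost without 1 to 3 libraries, among them BCAS IF day 1 replicate 1, sham IF day 7 replicate 1, sham IF day 14 replicate 3 and BCAS IF day 14 replicate 4.

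On single days under IF, 1 gene passed on day 1, the cytoskeletal linker gene Msn (0.37 ± 0.07, adjusted p = 0.0152), while 590 had an unadjusted p under 0.05 and 12 passed without a filter on low values. The Msn call was lost without sham IF replicate 2 or 4 or BCAS IF replicate 1 or 4, and 2 genes passed without sham IF replicate 1. None of the 14 protease genes passed on that day, and 2 rose adjusted over the list alone (median 0.11, camera adjusted p = 0.0025, or adjusted p = 0.0427 with an estimated correlation). On day 7 24 genes passed, 17 higher and 7 lower. Without a filter the balance turned and 142 passed, 44 higher and 98 lower. Wfdc6a (1.17 ± 0.23), Pi15 (0.98 ± 0.22), Fmo2 (0.98 ± 0.21), Cyp4b1 (0.95 ± 0.19) and Acer2 (0.82 ± 0.15) rose, and Cck (-1.23 ± 0.28), the transferrin receptor gene Tfrc (-0.53 ± 0.11), Smad6, Arhgef10l and the thyroid hormone receptor gene Thra (-0.36 ± 0.08) fell. The day 7 count was 5 and 12 without sham IF replicates 1 and 2, and 12, 1 and 10 without BCAS IF replicates 1, 2 and 4, and 0 in a limma fit of only the compared groups (898 at an unadjusted p under 0.05). All calls named for day 7 were lost without BCAS IF replicate 2 and without at least 1 further library. No gene passed in limma on day 14 (490 at an unadjusted p under 0.05) or day 21 (899), and limma-voom also called 0 on both days. Without a filter limma called 10 on each. Without BCAS IF replicate 3 on day 14 1 gene passed. The smallest p-values were those of Crispld2 (0.56 ± 0.12, adjusted p = 0.145) and Cnih4 on day 14. On day 21 they were those of Mafg (-0.33 ± 0.07, adjusted p = 0.206) and Cntfr (-0.45 ± 0.10, adjusted p = 0.381). On day 30 14 genes passed, 9 higher and 5 lower, against 36 without a filter, and 5 higher and 6 lower with the brain tissue score as a covariate. Crispld2 (0.97 ± 0.12, adjusted p = 5.21e-07), Ptp4a3 (0.92 ± 0.14), Ptgr1, Cdh13 and Lsp1 rose, and 2210407C18Rik, Tceal6 (-0.94 ± 0.18), Gpm6a and Id4 fell. The day 30 count was 6 without sham IF replicate 2, 3 or 4 or BCAS IF replicate 4, 8 without BCAS IF replicate 3, 29 without BCAS IF replicate 2, and 6 in a fit of only the compared groups. The calls of Ptgr1, Cdh13, Lsp1, Gpm6a and Id4 were lost without sham IF replicate 3 or 4 or BCAS IF replicate 4, and that of Tceal6 without sham IF replicate 2.

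**Figure D2:**
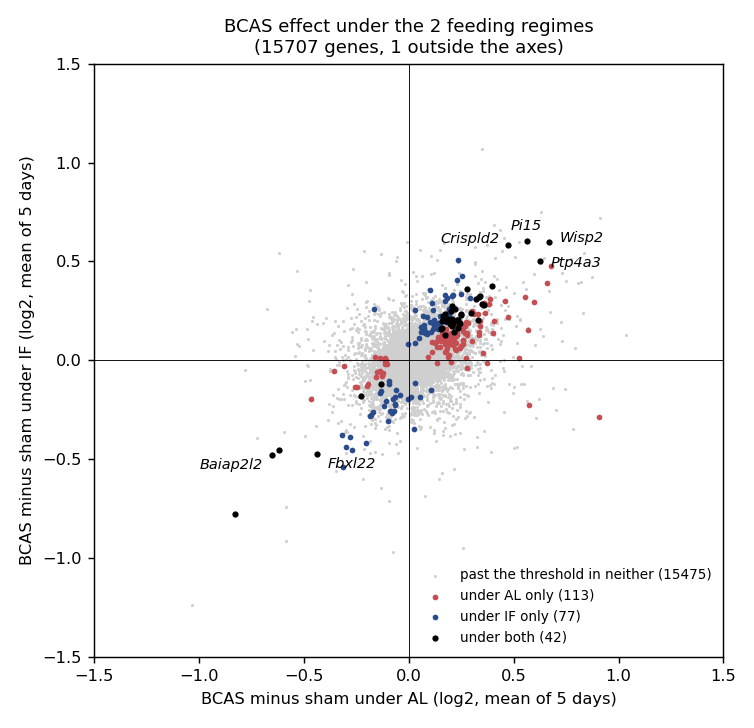
Log2 change with BCAS as the mean over 5 days under IF (vertical) against AL (horizontal) for 15707 genes, with genes past the threshold under AL only (113), under IF only (77) and under both (42) marked, and 1 gene outside the axes. Ptp4a3, Crispld2, Pi15 and Wisp2 lay high and Fbxl22 and Baiap2l2 low on both axes.

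The BCAS effects under the diets were compared directly, with no library in common. Of the genes past the threshold, 36 rose and 6 fell under both diets, where independent lists would share 0.673 and 0.0612, and none went in opposite directions. Ptp4a3, Crispld2, Pi15, Wisp2, Angpt2, Pgf and Cacna1c were among the shared rises, and Baiap2l2 and Fbxl22 among the shared falls. Of the 232 genes called under either diet, 93.1% had the same sign under both. Across all genes, which are not independent replicates, the correlation of the log2 changes was 0.359 (Spearman 0.341), and 0.275 to 0.393 with any 1 library left out. The interaction of BCAS and diet passed for 2 genes as the mean over days. The BCAS effect on the transcription factor gene Myc was -0.17 ± 0.06 under AL (adjusted p = 0.186) and 0.26 ± 0.06 under IF (interaction 0.42 ± 0.08, adjusted p = 0.0274). For Thra it was 0.11 ± 0.04 under AL (adjusted p = 0.16) and -0.15 ± 0.04 under IF (interaction -0.26 ± 0.05, adjusted p = 0.0274). Myc was at 2.31 ± 0.484 FPKM in sham AL, 1.92 ± 0.266 in BCAS AL, 1.84 ± 0.386 in sham IF and 2.40 ± 0.592 in BCAS IF. The interactions of Cldn5 (-0.18 ± 0.09), Ptp4a3, Crispld2, Pi15 and Wisp2 did not pass (adjusted p = 0.999 each), and 629 genes had an unadjusted p under 0.05, below the share of 0.05 that chance gives. Without a filter on low values no gene passed in limma (1362 at an unadjusted p under 0.05), and limma-voom called 1. The fall of Thra under IF lost its call without sham IF day 7 replicate 3. The interaction calls of Myc and Thra were each lost without 1 of 6 and 10 single libraries. None passed without sham IF day 1 replicate 2, BCAS IF day 1 replicate 2, sham IF day 7 replicate 3, sham IF day 14 replicate 3, BCAS AL day 21 replicate 2 or BCAS IF day 30 replicate 3. Only 1 passed without BCAS AL day 1 replicate 3, BCAS AL day 7 replicate 2 or 4 or BCAS IF day 21 replicate 2.

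Whether the BCAS effect differed between days was tested within each diet. Under AL 310 genes passed, led by Dnajb4 (adjusted p = 1.15e-06), Lars2 (adjusted p = 1.07e-05), Dnajb1 (adjusted p = 1.18e-05), Snx18 (adjusted p = 3.59e-05) and Dbp (adjusted p = 0.000424). Dnajb1 changed by 0.81 on day 14 and -1.06 on day 30, and Dbp by -1.40 on day 1. Lars2 fell on day 7, against the sham AL group that holds short-gene-rich libraries. The count was 839 without sham AL day 7 replicate 1, 184 without sham AL day 30 replicate 1, 92 in a fit of only the AL groups and 64 with the clock score as a covariate. Dbp, which did not pass there, is a member of that score. Under IF no gene passed in limma or in limma-voom, while limma without a filter on low values called 8. With the filter 794 had an unadjusted p under 0.05, the smallest for the collagen cross-linking gene Lox (adjusted p = 0.0831), Wfdc6a (adjusted p = 0.165), and Arhgef19 and Gm9493 among those at an adjusted p of 0.452. Under IF 2 genes passed without sham IF day 7 replicate 2 or 3 or BCAS IF day 14 replicate 3. The count was 1 without sham IF day 1 replicate 3, sham IF day 7 replicate 1, sham IF day 14 replicate 3, BCAS IF day 14 replicate 1, sham IF day 21 replicate 3 or BCAS IF day 30 replicate 1. The daily effects correlated weakly between days across genes, with a median r of 0.06 (-0.13 to 0.24) over 10 pairs of days under AL and 0.05 (-0.01 to 0.14) under IF. Genes called on at least 1 day numbered 567 under AL and 38 under IF, and this difference in number was not tested itself. The number under AL holds the 413 genes of day 7, for which chance could not be excluded. The interaction passed for 0, 5, 0, 0 and 0 genes on days 1, 7, 14, 21 and 30 (927, 1837, 886, 697 and 1016 at an unadjusted p under 0.05).

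**Figure D3:**
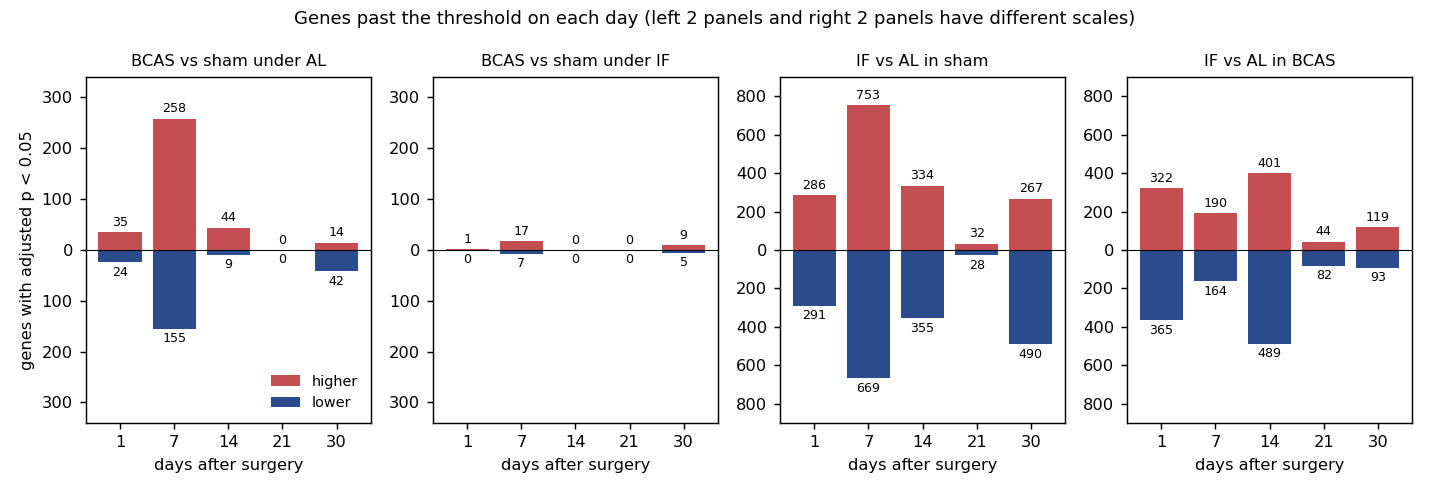
Number of genes past the threshold, higher (upward bars) and lower (downward bars), in each of the 4 comparisons on each day, with a wider scale for fasting than for BCAS. BCAS under AL reached 413 genes on day 7 and 0 on day 21, and fasting in sham reached 1422 genes on day 7 and 60 on day 21. Chance could not be excluded for either number of day 7.

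More genes passed with fasting than with BCAS, a difference in number that was not itself tested. In sham mice, as the mean over the 5 days, the clock output gene Dbp rose from 11.5 ± 8.06 FPKM (SD, n = 20) under AL to 39.2 ± 9.25 FPKM (n = 19) under IF, a log2 change of 1.89 ± 0.12 or 3.71-fold (adjusted p = 4.04e-20). Nfil3, which encodes a repressor of the genes that Dbp activates, fell by 1.58 ± 0.08 from 14.5 ± 5.28 to 4.01 ± 1.1 FPKM (adjusted p = 4.67e-24). The heat shock genes Hspa1b, Hspa1a, Hsph1 and Dnaja1 fell by 1.39 ± 0.18, 1.24 ± 0.16, 1.01 ± 0.09 and 0.86 ± 0.08, and the cold-inducible RNA-binding gene Cirbp rose by 0.98 ± 0.10 from 26.7 ± 5.54 to 56.3 ± 20.7 FPKM. The methyltransferase gene Inmt rose by 1.47 ± 0.09, and Ackr1, a chemokine-binding receptor gene of venous endothelium, fell by 1.42 ± 0.34. Hspa1a and Hspa1b are near-identical copies, so their separate values are uncertain. On GRCm38, Dbp (ENSMUSG00000059824) lies on chromosome 7 at 45705088 to 45710203 and Nfil3 (ENSMUSG00000056749) on chromosome 13 at 52967209 to 52981073. Hspa1b lies on chromosome 17 at 34956436 to 34959238, Cirbp on chromosome 10 at 80165985 to 80172786 and Inmt on chromosome 6 at 55170626 to 55175043. In all 3719 genes passed, 23.7% of those tested, 1850 higher and 1869 lower, of which 51 rises and 39 falls exceeded 1.5-fold.

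Of 20 clock genes in sham, 14 rose and 5 fell with fasting, over all genes and adjusted over the list alone, with a median of 0.51 (camera adjusted p = 1.04e-07, or adjusted p = 0.0043 with an estimated correlation). Per3 (1.05 ± 0.05), Tef (0.93 ± 0.05), Per2 (0.86 ± 0.08), Nr1d2 (0.83 ± 0.06) and Ciart (1.13 ± 0.13) rose, and the activators Arntl (-1.06 ± 0.07) and Npas2 (-0.92 ± 0.07) fell. All 15 heat shock chaperone genes fell, over all genes and adjusted over the list alone, with a median of -0.56 (camera adjusted p = 2.89e-24, or adjusted p = 0.00715 with an estimated correlation), among them Hspa8 (-0.68 ± 0.06) and Chordc1 (-0.60 ± 0.05). Of 15 genes of the unfolded protein response 10 fell, none rose and 5 did not pass, with 12 falls adjusted over the list alone and a median of -0.30 (camera adjusted p = 4.06e-08, or adjusted p = 0.119 with an estimated correlation). Its examples were Sdf2l1 (-0.77 ± 0.10), Xbp1 (-0.36 ± 0.05), Calr (-0.38 ± 0.06) and Atf4 (-0.30 ± 0.04). Of 21 cholesterol synthesis genes 13 fell and none rose, with 15 falls adjusted over the list alone and a median of -0.21 (camera adjusted p = 3.13e-08, or adjusted p = 0.119 with an estimated correlation), among them Cyp51 (-0.50 ± 0.06), Hmgcs1 (-0.30 ± 0.04) and the regulator Srebf2 (-0.21 ± 0.03). A second cold-inducible RNA-binding gene, Rbm3, chosen after its values were seen, rose by 0.53 ± 0.06 from 11.3 ± 1.94 to 17.1 ± 4.57 FPKM.

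Of 21 genes of fatty acid oxidation 8 rose and 1 fell in fasted sham mice, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.0259, or adjusted p = 0.557 with an estimated correlation). The uncoupling protein gene Ucp2 (0.31 ± 0.05), the fatty acid uptake gene Cd36 (0.30 ± 0.06) and Cpt1a (0.13 ± 0.03) rose, and the lipid droplet gene Plin2 (-0.13 ± 0.03) fell. Of 16 cytokine and adhesion genes 8 fell and 1 rose, or 10 and 3 adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.0355, or adjusted p = 0.574 with an estimated correlation). The interleukin gene Il1b fell by 0.32 ± 0.08, the chemokine gene Ccl7 by 0.47 ± 0.11, the adhesion gene Sele by 0.43 ± 0.11 and Ptgs2 by 0.43 ± 0.11, while Icam1 was at -0.26 ± 0.11 (adjusted p = 0.0712). Of 19 fibrillar and elastic matrix genes 5 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0331, or adjusted p = 0.776 with an estimated correlation), including Thbs1 (-0.82 ± 0.09), Lox (-0.47 ± 0.06) and Loxl2 (-0.23 ± 0.06). Of 18 immediate early genes 6 fell and 1 rose, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0211, or adjusted p = 0.776 with an estimated correlation), with Atf3 (-0.73 ± 0.18), Npas4 (-0.43 ± 0.08) and Klf4 (-0.39 ± 0.07) among the falls. Of 78 ribosomal protein genes 8 rose and 2 fell, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.000149, or adjusted p = 0.915 with an estimated correlation).

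Lists whose camera test did not pass also held changed members in sham. Of 14 protease and inhibitor genes 4 fell and 2 rose, or 4 and 3 adjusted over the list alone, including the plasminogen activator genes Plat (-0.45 ± 0.04, adjusted p = 1.54e-13) and Plau (-0.30 ± 0.06), Adamts1 (-0.50 ± 0.10) and Timp4 (0.36 ± 0.07). Of 13 p53 targets 7 fell and 2 rose by both counts, including the cell cycle inhibitor gene Cdkn1a (-0.58 ± 0.09), Fas (-0.34 ± 0.06) and Mdm2 (-0.17 ± 0.03). Of 17 antioxidant genes 4 rose by both counts, including Osgin1 (0.51 ± 0.07) and Nqo1 (0.28 ± 0.06). Of 12 FoxO and insulin-responsive genes 2 rose, Txnip (0.57 ± 0.05) and Pik3ip1 (0.51 ± 0.06), and 3 fell, by both counts. In the hypoxia list of 21, P4ha1 fell (-0.64 ± 0.06) and Pdk1 rose (0.36 ± 0.05), among 5 rises and 3 falls, or 6 and 5 adjusted over the list alone. The gap junction gene Gja5 (-0.42 ± 0.08), the smooth muscle regulator Myocd (-0.34 ± 0.07) and Tgfb3 (-0.33 ± 0.08) fell, and Pgf rose (0.34 ± 0.05), whereas Acta2 (-0.04, adjusted p = 0.782) and Myh11 (0.08, adjusted p = 0.529) did not pass. The clock score of every IF group lay above that of every AL group, and with it as a covariate 2 of the 3719 genes passed. No named fasting call of the mean over days in sham was lost by leaving out 1 library.

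**Figure D4:**
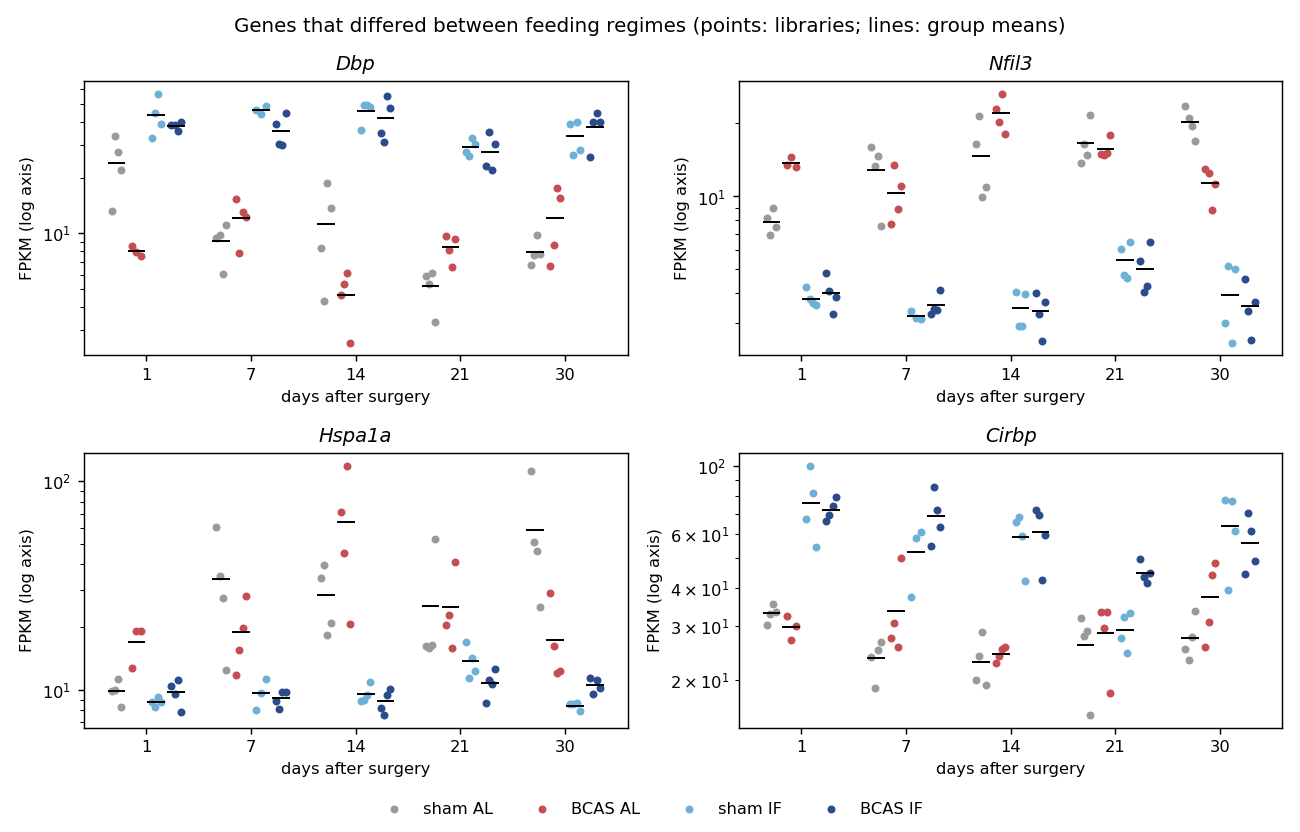
FPKM on a log axis of Dbp, Nfil3, Hspa1a and Cirbp in each of the 78 libraries (points), by surgery, diet and day after surgery, with lines for group means. Dbp had means of 39.2 and 36.3 FPKM in the IF arms against 11.5 and 9.12 FPKM in the AL arms.

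In BCAS mice fasting gave 3623 genes past the threshold, 23.1% of those tested, 1752 higher and 1871 lower, of which 38 rises and 47 falls exceeded 1.5-fold. Dbp rose by 1.96 ± 0.12 from 9.12 ± 3.95 FPKM (n = 19) to 36.3 ± 8.25 FPKM (n = 20), Inmt by 1.45 ± 0.09, Per3 by 1.28 ± 0.05 (adjusted p = 4.57e-29). Ciart rose by 1.20 ± 0.13, Tef and Tspan4 by 1.13 ± 0.05, Per2 by 1.12 ± 0.08, Cirbp by 0.97 ± 0.10, Tcap by 0.95 ± 0.12 and Nr1d2 by 0.87 ± 0.06. Nfil3 fell by 1.64 ± 0.08, Hspa1b by 1.49 ± 0.18, Ackr1 by 1.34 ± 0.34, Arntl by 1.29 ± 0.07, Hspa1a by 1.15 ± 0.16, Npas2 by 1.11 ± 0.07, Hsph1 and Spon2 by 1.09, Foxs1 by 0.99 ± 0.10 and Rasl11a by 0.88 ± 0.09. Rbm3, chosen after its values were seen, rose by 0.60 ± 0.06. All 15 heat shock chaperone genes fell by both counts, with a median of -0.52 (camera adjusted p = 2.87e-24, or adjusted p = 0.00714 with an estimated correlation), including Hspa8 (-0.77 ± 0.06). Of 20 clock genes 14 rose and 4 fell by both counts, with a median of 0.45 (camera adjusted p = 4.99e-09, or adjusted p = 0.00111 with an estimated correlation). Of 15 genes of the unfolded protein response 11 fell, or 13 adjusted over the list alone, with a median of -0.39 (camera adjusted p = 6.19e-12, or adjusted p = 0.0263 with an estimated correlation), including Sdf2l1 (-0.94 ± 0.10), Creld2 (-0.62 ± 0.08), Calr (-0.49 ± 0.06) and Xbp1 (-0.39 ± 0.05). Of 21 cholesterol synthesis genes 8 fell, or 9 adjusted over the list alone, including Cyp51 (-0.33 ± 0.06) and Srebf2 (-0.17 ± 0.03), with camera adjusted p = 0.00327, or adjusted p = 0.585 with an estimated correlation.

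Lists without a camera call in BCAS mice again held changed members. Plat fell by 0.60 ± 0.04 from 50.5 ± 4.0 to 33.2 ± 3.33 FPKM (adjusted p = 4.53e-19) and Plau by 0.45 ± 0.06, in a protease list with 2 rises and 4 falls of 14, or 2 and 5 adjusted over the list alone. Thbs1 (-0.84 ± 0.09) and Lox (-0.44 ± 0.06) were among 5 falls of 19 matrix genes, and Cdkn1a (-0.86 ± 0.09) among 6 falls of 13 p53 targets, of which Sesn2 rose (0.24 ± 0.05). Il1b (-0.32 ± 0.08), Cxcl1 (-0.69 ± 0.21) and Selp (-0.37 ± 0.12) were the 3 of 16 cytokine and adhesion genes that fell. Of 15 TGF-β genes 5 fell, including Tgfb3 (-0.55 ± 0.08) and Tgfb2 (-0.26 ± 0.05), and 2 rose. Of 10 arterial endothelial genes 5 fell, including Gja5 (-0.39 ± 0.08), Vegfc (-0.36 ± 0.08) and the Notch target Hey1 (-0.27 ± 0.06). Of 21 fatty acid oxidation genes 8 rose, including Ucp2 (0.38 ± 0.05), and Plin2 fell (-0.16 ± 0.03). Txnip (0.55 ± 0.05), Pik3ip1 (0.49 ± 0.06), Pdk1 (0.43 ± 0.05), Osgin1 (0.43 ± 0.07), Nqo1 (0.32 ± 0.06) and the glucocorticoid-responsive gene Fkbp5 (0.45 ± 0.12) rose, and P4ha1 (-0.63 ± 0.06), Klf4 (-0.46 ± 0.07), Atf3 (-0.66 ± 0.18) and Myocd (-0.33 ± 0.07) fell. Adjusted over the list alone, the counts of rises and falls were 0 and 5 for matrix, 2 and 6 for p53 targets, 0 and 3 for cytokines, 2 and 5 for TGF-β, 2 and 5 for arterial endothelium and 8 and 1 for fatty acid oxidation. Acta2 (-0.15 ± 0.09, adjusted p = 0.215) and Myh11 (0.09, adjusted p = 0.487) did not pass. With the clock score, which lay higher in every IF group than in every AL group, as a covariate none of the 3623 genes passed in limma, and 1251 genes had an unadjusted p under 0.05.

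**Figure D5:**
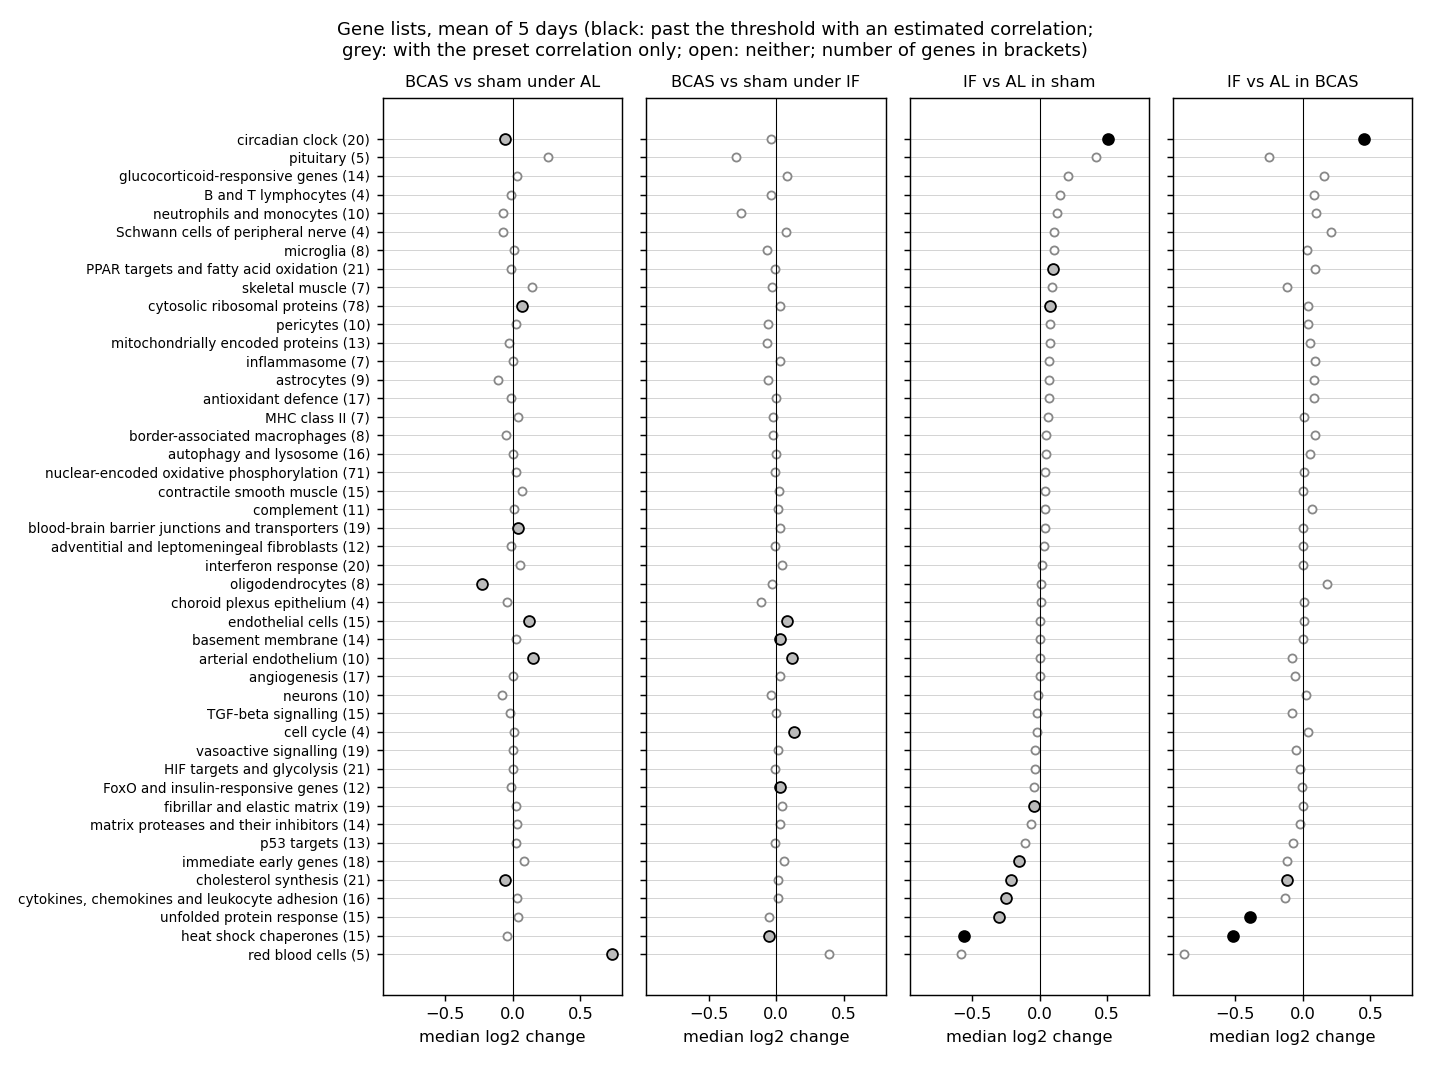
Median log2 change of the tested gene lists in the 4 comparisons averaged over days, with black marks for lists past the threshold with an estimated correlation in camera, grey marks for lists past it at the preset correlation only, and open marks for the others. The heat shock list had medians of -0.56 and -0.52 and the clock list 0.51 and 0.45 with fasting in sham and BCAS.

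Genes passed with fasting on each day, although chance could not be excluded for the number in sham on day 7. On all 5 days 16 genes in sham and 21 in BCAS passed, among them Dbp, Per3, Tef, Inmt, Tspan4, Arntl, Nfil3 and Foxs1 in both. In sham 577, 1422, 689, 60 and 757 genes passed on days 1, 7, 14, 21 and 30, and in BCAS 687, 354, 890, 126 and 212. On day 1 in sham Inmt (1.40 ± 0.19), Tcap (1.23 ± 0.27), Cirbp (1.14 ± 0.21), Per1 (1.03 ± 0.22) and Rbm3 (0.99 ± 0.13) rose, and Hist2h3c2, Lypd2, Sdf2l1 (-1.03 ± 0.22), Spon2 and Nfil3 fell. On day 7 in sham the neuropeptide gene Oxt (2.45 ± 0.79), Dbp (2.26 ± 0.28), Ciart (1.61 ± 0.31), Tcap and Inmt rose, and Lars2 (-2.45 ± 0.38), Hspa1b (-1.77 ± 0.43), Hspa1a, Nfil3 and Arntl fell, with the short-gene-rich libraries in sham AL. On day 14 in sham Dbp (2.08 ± 0.26) and Inmt (1.72 ± 0.19) rose, and Ackr1 (-3.34 ± 0.75), the lipocalin gene Lcn2 (-3.28 ± 0.97), Hspa1b and Serpina3f (-1.58 ± 0.48) fell. On day 21 in sham Dbp (2.31 ± 0.26), Inmt (1.33 ± 0.19), Nr1d2 (1.19 ± 0.14) and Per3 (1.16 ± 0.12) rose, and Nfil3 (-1.44 ± 0.18), Thbs1 (-1.07 ± 0.20), Npas2, Arntl and Foxs1 fell. On day 30 in sham Dbp (1.93 ± 0.26), Inmt (1.59 ± 0.19), Per3 and Cirbp rose, and Hspa1b (-2.50 ± 0.40), Hspa1a (-2.46 ± 0.35), Nfil3 (-2.15 ± 0.18), Atf3 (-1.58 ± 0.39) and Dnaja1 (-1.52 ± 0.17) fell. Of these daily calls in sham, those of Lypd2 (without sham AL replicate 1), Tcap on day 1 (sham IF replicate 2 or 3), Foxs1 (sham AL replicate 3, sham IF replicate 2 or 3) and Atf3 (sham AL replicate 1, sham IF replicate 4) rested on single libraries. Those of Oxt, Lcn2 and Serpina3f were lost without any 1 of 5 or 6 libraries. In sham on day 7 753 genes were higher and 669 lower, but 128 were higher and 168 lower of the 296 that passed without the short-gene-rich libraries. Fits of only the compared groups gave 27, 1, 357, 24 and 409 genes on the 5 days in sham and 255, 137, 461, 20 and 60 in BCAS. Leaving out single libraries moved the sham counts by over 1.5 times as follows. Day 1 gave 138 and 323 without sham AL replicates 1 and 4 and 184 and 194 without sham IF replicates 2 and 3. Day 7 gave 2625 and 574 without sham AL replicates 1 and 4 and 2997, 440 and 265 without sham IF replicates 1, 2 and 3. Day 14 gave 332 without sham AL replicate 1 and 440 and 381 without sham IF replicates 1 and 2. Day 21 gave 34 without sham AL replicate 4 or sham IF replicate 3 and 37 without sham IF replicate 2. Day 30 gave 344 without sham AL replicate 1 and 407 without sham IF replicate 3.

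In BCAS mice, fasting on day 1 raised Dbp (2.12 ± 0.28), Inmt (1.90 ± 0.21), Ciart, Per3 and Rbm3 (1.34 ± 0.15) and lowered Hba-a2 (-3.55 ± 0.89), Hba-a1 (-3.48 ± 0.94), Hbb-bs, Hbb-bt and Sdf2l1 (-1.61 ± 0.24). The 4 globin calls were lost without BCAS AL replicate 2 or 3, those of Hba-a1, Hbb-bs and Hbb-bt also without BCAS IF replicate 1, and that of Hbb-bs without BCAS IF replicate 3. They were made against the BCAS AL libraries of day 1, in which the amount of blood was not measured. Without the short-gene-rich libraries 389 genes passed on this day. On day 7 Wfdc6a (1.33 ± 0.22), Dbp (1.51 ± 0.26), Inmt, Per2 and CR974586.3 rose, and Arntl (-1.37 ± 0.15), Nfil3, Spon2 (-1.25 ± 0.17), Npas2 and Sdf2l1 fell. On day 14 Dbp (2.94 ± 0.26), Inmt (1.74 ± 0.19), Per3 (1.57 ± 0.12), Tef and Nr1d2 rose, and Hspa1b (-2.69 ± 0.40), Ackr1 (-2.50 ± 0.75), Hspa1a (-2.47 ± 0.35), Nfil3 (-2.39 ± 0.18) and Cxcl1 (-1.80 ± 0.45) fell. On day 21 Dbp (1.59 ± 0.26), Wfdc2 (1.09 ± 0.27), Tspan4, Per3 and Tef rose, and Nfil3 (-1.48 ± 0.18), Thbs1 (-1.17 ± 0.20), Cdkn1a (-1.11 ± 0.19), Arntl and Gem fell. On day 30 Dbp (1.63 ± 0.26), Inmt (1.40 ± 0.19), Per2, Ciart and Per3 rose, and Nfil3 (-1.45 ± 0.18), Sdf2l1 (-1.30 ± 0.22), Arntl, Npas2 and Rasl11a fell. The calls of Ciart on day 1 and Cxcl1 were lost without BCAS AL replicate 3, those of Gem and Wfdc2 without BCAS AL replicate 2, and that of Ciart on day 30 without BCAS AL replicate 2 or BCAS IF replicate 3. Those of CR974586.3 and Ackr1 were lost without any 1 of 6 libraries. On day 21 in sham Cirbp was at 24.5 to 33.1 FPKM in IF and 15.4 to 31.9 FPKM in AL (0.20 ± 0.21, adjusted p = 0.8). Heat shock chaperone genes that fell numbered 6, 11, 12, 0 and 14 of 15 on the 5 days in sham and 11, 6, 14, 3 and 4 in BCAS. The camera call of this list held with an estimated correlation in sham on days 14 (adjusted p = 0.00874) and 30 (adjusted p = 0.00213) and in BCAS on days 1 (adjusted p = 0.0335), 7 (adjusted p = 0.0499) and 14 (adjusted p = 0.0012). Leaving out single libraries gave, on day 1, 257 and 262 genes without BCAS AL replicates 2 and 3 and 452 and 433 without BCAS IF replicates 1 and 3. Day 7 gave 226, 218 and 218 without BCAS AL replicates 1, 2 and 3 and 199 without BCAS IF replicate 2. Day 14 gave 524 without BCAS AL replicate 1 and 568 without BCAS IF replicate 2. Day 21 gave 58 and 39 without BCAS AL replicates 2 and 4 and 73, 73 and 46 without BCAS IF replicates 1, 2 and 4. Day 30 gave 124 and 95 without BCAS AL replicates 1 and 2 and 108 and 133 without BCAS IF replicates 3 and 4.

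The fasting effects in sham and BCAS mice, which shared no library, were compared across genes. Of the genes past the threshold, 1172 rose and 1232 fell in both, where independent lists would share 206 and 223, and 1 went in opposite directions. Of the 4937 called in either, 97% had the same sign in both. The correlation of the log2 changes was 0.717 (Spearman 0.698) across 15707 genes, and 0.693 to 0.724 with any 1 library left out. Some BCAS genes were also looked up for fasting after their values were seen. Wisp2, which rose with BCAS, also rose with fasting, by 0.81 ± 0.11 in sham and 0.73 ± 0.11 in BCAS, and was highest in BCAS IF at 40.3 ± 12.2 FPKM (n = 20) against 14.5 ± 3.68 FPKM (n = 20) in sham AL. Ptp4a3 rose with fasting by 0.32 ± 0.06 in sham and 0.19 ± 0.06 in BCAS. Pi15 and Angpt2, which also rose with BCAS, did not pass with fasting in sham (adjusted p = 0.742 and 0.84).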

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

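The tests with the clock score and those without the libraries rich in fragments of short genes were chosen after the results were seen.

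As the mean over days fasting lowered heat shock genes, raised the cold-inducible genes Cirbp and Rbm3, the latter chosen after its values were seen, and shifted clock genes, and with the brain tissue score as a covariate 100% of the 71 calls of these groups stood, which argues against brain tissue as the whole cause. On day 21, with clock scores of 1.05 in sham IF and -2.41 in sham AL, 0 of 15 heat shock genes passed in sham (median -0.17) and 3 in BCAS (-0.31), while Cirbp was at 0.20 ± 0.21 and 0.67 ± 0.21 and Rbm3 at 0.08 ± 0.13 and 0.00 ± 0.13. On day 14 in sham the clock scores were 1.85 in IF and -1.61 in AL. The mean z-score of the heat shock genes was then -0.825 to -0.521 in IF and 0.509 to 1.429 in AL. On day 21 in sham it overlapped, at -0.075 to 0.67 in IF and 0.194 to 1.764 in AL. For sham mice this argues against clock phase alone as the cause of the heat shock change. With the clock score as a covariate the median of the heat shock genes in sham went from -0.56 with a median SE of 0.06 to -0.25 with 0.16, and 0 of 15 passed. This fit could not tell clock phase, from the time of collection or from feeding, apart from fasting, as the score lay higher in every IF group. The time of collection was not given. After group means were removed, the heat shock and cold-inducible scores of the 78 libraries had r = -0.46 (permutation p = 3e-05, adjusted p = 9e-05 over 3 relations, rho = -0.56 with permutation p = 2e-05, r = -0.45 without 2 libraries), which is consistent with a shared state such as body temperature as a hypothesis. The clock score had r = -0.21 with the heat shock score (permutation p = 0.0703, adjusted p = 0.105, rho = -0.35 with permutation p = 0.00614, r = -0.30 without 2 libraries) and r = 0.21 with the cold-inducible score (permutation p = 0.109, adjusted p = 0.109, rho = 0.32 with permutation p = 0.0129, r = 0.39 without 2 libraries), so a part of clock phase in this relation stayed open.

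Many genes passed on day 7 in comparisons with sham AL. Without its replicates 2 and 4, which were rich in fragments of short genes, 76.5% of the 413 genes of BCAS under AL kept at least 50% of their change, against 81.8% to 100% for the other pairs left out. The count of genes was 72 without this pair, 206 and 30 without the other pairs that hold replicate 4, and 2221, 3049 and 632 without the pairs that do not hold it. With the brain tissue score as a covariate 39.2% still passed, below the share set before the fit as the sign of brain tissue. However, 98.3% kept at least 50% of their change, and the median ratio of the changes with and without the score was 0.97. The median size went from 0.37 (median SE 0.096) to 0.34 (0.101), so this score took up little of the size of the changes. The share and the sizes went different ways and did not decide on brain tissue. Library quality, brain tissue and a response to BCAS at day 7 all stayed open. The low smooth muscle and high fibroblast values of sham AL replicate 4 were not tested as a cause.

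The BCAS effect under AL differed between days in 310 genes. With the clock score as a covariate 59 of them (19%) still passed, against 105 to 310 genes with 20 random scores. The random scores were not matched to the differences of the clock score between AL groups, such as -0.03 in sham and -1.83 in BCAS on day 1. They therefore cannot show a loss particular to the clock. The 19% was below the share set before the fit as the sign of clock phase, but the median SD between days only went from 0.21 to 0.20. Without the 3 libraries rich in fragments of short genes 50.3% still passed. A difference in clock phase between AL groups, library quality and a time course of BCAS stayed open, since none of these values decided between them.

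The interaction of BCAS and diet had an adjusted p of 0.0274 for Myc and 0.0274 for Thra as the mean over days. On any day it passed for 7 genes, and 1355 had an unadjusted p under 0.05. These were Malat1 (adjusted p = 3e-05), Snx18 (adjusted p = 0.00679), and Ube2h, Dnajb1, Dnajb4, Gm10175 and Myc (adjusted p = 0.0225 each). The calls of Malat1 and Snx18 held without any 1 library. Without the 3 libraries rich in fragments of short genes, 2 of them in sham AL on day 7, 11 genes passed and that of Myc was lost (adjusted p = 0.0556), while Malat1 was at an adjusted p of 0.00178. Over all alternatives apart from single libraries left out, the adjusted p was 0.0224 to 0.061 for Myc and 2.68e-05 to 0.00178 for Malat1. Without a filter Dnajb1, Dnajb4, Gm10175 and Myc lost their calls, and with limma-voom Dnajb1, Gm10175, Myc and Ube2h did. The non-coding genes Malat1 and Gm10175 were chosen after their values were seen. On day 7 the BCAS effect on Malat1 was -1.61 ± 0.17 under AL and 0.46 ± 0.18 under IF, and that on Myc was -0.33 ± 0.13 and 0.61 ± 0.14. The effect on Malat1 under AL was -1.36 without the short-gene-rich libraries (adjusted p = 1.03e-05), and its call was lost in a fit of only the compared groups (adjusted p = 0.182, the highest of these alternatives, against 6.17e-10 for the lowest). On day 30 the effect on Dnajb1 was -1.06 ± 0.17 under AL and 0.12 ± 0.17 under IF. The any-day count was 12 without sham AL day 7 replicate 1 or sham AL day 14 replicate 2, 14 without sham IF day 7 replicate 1, 2 without sham AL day 30 replicate 1, and 3 without replicate 4 of sham IF, BCAS AL or BCAS IF on day 30.

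Single libraries stood apart from the others of their group in 12 of 126 tests of 7 measures in groups of 4, where chance gives about 1 in 20. Fragments in units of M were 25.9 in sham IF day 1 replicate 1 (others 16.6 to 18.1), 15.9 in sham IF day 14 replicate 4 (23.4 to 23.9), 23.1 in sham IF day 21 replicate 2 (21.1 to 21.4) and 23.2 in sham AL day 30 replicate 4 (15.8 to 16.2). The share in genes under 300 bases was 0.106% in BCAS IF day 1 replicate 3 (0.057% to 0.06%) and 0.076% in BCAS IF day 7 replicate 2 (0.057% to 0.059%). Mitochondrial genes took 4.62% in BCAS IF day 21 replicate 4 (6.45% to 6.6%), and Ptgds took 9.21% in sham IF day 1 replicate 2 (6.01% to 6.47%). The median correlation with the other libraries was 0.963 in sham AL day 21 replicate 4 (0.9806 to 0.9817). It was lower, at 0.9391, in sham AL day 7 replicate 4 (0.9693 to 0.979), where the gap was too small for this test. The brain tissue score was 1.903 in sham IF day 14 replicate 1 (-0.052 to 0.121) and -0.755 in sham IF day 30 replicate 1 (0.333 to 0.443), and the clock score was -1.574 in BCAS AL day 7 replicate 2 (-1.007 to -0.916).

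Other splits of the same libraries into groups of the same sizes were also counted. Within days the lowest share possible was 1 of 35, and shares were not corrected for the number of results examined. Chance was taken as unlikely where only the real split gave as many genes. This held for BCAS under AL on days 1 (59 genes, highest other 7), 14 (53, 3) and 30 (56, 12) and under IF on day 30 (14, 4). For fasting in sham it held on days 1 (577, 16), 14 (689, 70), 21 (60, 3) and 30 (757, 58), and in BCAS on all 5 days (687, 91; 354, 2; 890, 22; 126, 1; 212, 8). Chance could not be excluded for BCAS under AL on day 7 (413 genes, 6 of 35 splits, highest other 2159), or under IF on days 1 (1, 12 splits, 4) and 7 (24, 3 splits, 558). It could not be excluded for fasting in sham on day 7 (1422, 6 splits, highest other 4222). A real count of 0 is reached by every split, so the splits decided nothing for BCAS under AL on day 21 (35 splits, highest other 2) or under IF on days 14 (35, 0) and 21 (35, 1). The high counts of other day 7 splits point to a structure among the libraries of that day.

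For results over all days 100 splits drawn within days were used. Chance was unlikely for BCAS under IF (119 genes, 1 split, highest other 1) and for fasting in sham (3719, 1, 779) and in BCAS (3623, 1, 2). The same held for the agreement of BCAS effects (0.359, 1, 0.19) and of fasting effects (0.717, 1, 0.188). For BCAS under AL (155 genes) 2 splits gave as many, but the highest other gave 573, which points to a structure of the samples. Only the real split gave as many genes for BCAS by day under AL (310, 1, 230) and the mean interaction (2, 1, 1). For the any-day interaction (7 genes) 2 splits did, with a highest other of 41. These splits shuffled surgery and so removed the whole BCAS effect. They could not test a difference between days or diets alone, and the margin for the mean interaction was 2 genes against 1. For BCAS by day under IF, with 0 genes, all 100 splits gave as many (highest other 2), so nothing was decided. Chance could not be excluded for the number of gene lists past the threshold at the preset correlation. These were 8 for BCAS under AL (44 splits, highest other 18), 6 under IF (70, 16), 9 for fasting in sham (36, 14), 4 in BCAS (93, 15) and 5 for the interaction (89, 16).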

How the results depend on the processing

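Chosen after the results were seen were the clock score, limma-voom, the fits without the 3 libraries rich in fragments of short genes and those without genes of near-zero variance. Median-ratio scaling and a pseudocount of 0.1 moved no count by over 1.5 times, and the brain score moved 1 of 28, BCAS under AL on day 7 (185). The scaling factors were only 0.967 to 1.02, so this scaling could change little. With median-ratio scaling 4 gene lists passed for BCAS under IF against 6, as the arterial endothelial and basement membrane lists lost their calls. Without a filter counts were, for BCAS under AL, 240 on day 1, 6 on day 21 and 103 for the mean, under IF 12, 142, 10, 10 and 36 on the 5 days and 74 for the mean, 0 for the mean interaction and 8 by day under IF. With only the compared groups they were, for BCAS under AL, 0 on days 1, 7 and 14, 5 on day 30 and 92 by day, and under IF 0 on day 7 and 6 on day 30. For fasting they were 27, 1, 357, 24 and 409 in sham and 255, 137, 461, 20 and 60 in BCAS. Such fits have fewer libraries to estimate the spread. The loss differed between days with similar numbers of libraries, however. Fasting in sham went from 689 to 357 genes on day 14 and from 1422 to 1 on day 7. Where groups vary more than the spread shared by all 20 groups, the main p-values are too small. The spread within groups was not tested itself. However, other splits of the day 7 libraries gave up to 4222 genes for fasting in sham and 2159 for BCAS under AL. On day 14 the highest other counts were 70 and 3. These values point to main p-values that were too small in these day 7 comparisons. In the fits of only the compared groups limma also raised near-zero variances, of 4 to 285 genes, none of which passed. Without these genes the counts for BCAS under AL were 1 on day 1, 0 on days 7 and 14, 7 on day 30 and 92 by day, and under IF 0 on day 7 and 6 on day 30. For fasting they were 25, 1, 366, 24 and 407 in sham and 264, 136, 476, 20 and 73 in BCAS. limma-voom gave 1 for the mean interaction and 3 for any day. Without the 3 libraries BCAS under AL gave 28 on day 1 and 72 on day 7, fasting 296 in sham on day 7 and 389 in BCAS on day 1, and the any-day interaction 11. With the clock score 2 genes passed for fasting in sham, 0 in BCAS and 64 for BCAS by day under AL. With an estimated correlation 0, 0, 2, 3 and 0 gene lists passed for BCAS under AL and IF, fasting in sham and BCAS, and the interaction.

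Of 397 calls of single genes examined in this way, 121 stood in all alternatives run. Calls ended for 24 with the brain score, 31 with limma-voom, 0 with median-ratio scaling, 50 without a filter, 118 with only the compared groups (117 without genes of near-zero variance), 11 with a pseudocount of 0.1, 34 without the 3 libraries, 132 of 137 with the clock score, and 121 without some single library. The fit with the clock score could not separate fasting from clock phase, so its losses do not speak against the fasting calls.

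No sign of a named call turned except with the clock score, where none of the turned values passed. In sham these were Cdkn1a 0.08, Ciart -0.62, Ctsd -0.06, Lox 0.01, Myocd 0.01, Nqo1 -0.09, Nr1d1 -0.15, Olfml3 -0.15, Osgin1 -0.02, Per1 -0.29, Tgfb3 0.08, Ttr -0.29 and Ucp2 -0.09. In BCAS they were Cd163 -0.23, Ciart -0.72, Fkbp5 -0.26, Hey1 0.04, Lox 0.08, Myocd 0.05, Nqo1 -0.08, Nr1d1 -0.55, Osgin1 -0.15, Per1 -0.36, Prx -0.06, Selp 0.53, Tgfb2 0.01 and Ucp2 -0.05. Ciart, Nr1d1 and Per1 are members of the score, so they were adjusted for their own values, and for the other genes the cause was not tested. Depth limited genes of low FPKM, for which single fragments set the value.

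Leaving out 1 library gave, for BCAS under AL, 1 to 80, 45 to 1750, 10 to 140, 0 to 1 and 7 to 54 genes on the 5 days, 86 to 188 for the mean and 184 to 839 by day. Under IF it gave 0 to 2, 1 to 20, 0 to 1, 0 to 0 and 6 to 29, 77 to 144 for the mean and 0 to 2 by day. Fasting gave 138 to 643, 265 to 2997, 332 to 711, 34 to 83, 344 to 768 and 3212 to 4260 for the mean in sham, and 257 to 716, 199 to 355, 524 to 825, 39 to 136, 95 to 228 and 3339 to 3659 in BCAS. The mean interaction gave 0 to 3, that of any day 2 to 14, and the agreements 0.275 to 0.393 and 0.693 to 0.724. Libraries that moved a count by over 1.5 times, or from 0, are named beside it.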

Other observations

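Further lists held members that changed with fasting, although their camera tests did not pass, and 23.7% of all genes tested passed in sham and 23.1% in BCAS. Of 14 glucocorticoid-responsive genes 4 rose and 2 fell in sham and 6 rose and 2 fell in BCAS, and adjusted over the list alone these were 6 and 2 in both (camera adjusted p = 0.356 and 0.147). In sham the kinase gene Pdk4 rose by 0.30 ± 0.09. Of 16 autophagy and lysosome genes 5 rose and 2 fell in sham and 5 rose and 1 fell in BCAS, or 7 and 2 and 5 and 1 adjusted over the list alone, with medians of 0.05 in both (camera adjusted p = 0.237 and 0.153). In sham the cargo receptor gene Sqstm1 rose by 0.10 ± 0.02 and the protease gene Ctsd by 0.12 ± 0.03. Of 8 microglial markers 4 rose and 1 fell in sham, also adjusted over the list alone (camera adjusted p = 0.38), with Olfml3 at 0.26 ± 0.06 and Tmem119 at 0.19 ± 0.04. In BCAS 2 of 4 measured Schwann cell markers rose with fasting, Egr2 (0.26 ± 0.09) and Prx (0.16 ± 0.05), and 4 did so adjusted over the list alone (camera adjusted p = 0.124). The Egr2 call was lost without 1 of 7 single libraries. The macrophage marker Cd163 rose by 0.41 ± 0.09 in BCAS.

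Of the brain markers, no member of the 10 neuronal genes passed in any of the 4 comparisons of means in limma (medians -0.08 and -0.04 for BCAS under AL and IF, and -0.01 and 0.02 for fasting in sham and BCAS). Of 9 astrocyte genes 1 rose with BCAS under AL (median -0.11), none passed under IF (-0.06), and with fasting 1 rose and 1 fell both in sham (0.07) and in BCAS (0.08). No member of the 8 oligodendrocyte genes passed in any of these comparisons (medians -0.23, -0.03, 0.01 and 0.18).

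The remaining genes of the fixed panel were read as means over days. With fasting, Per1 rose by 0.59 ± 0.10 in sham and 0.61 ± 0.10 in BCAS and Nr1d1 by 0.71 ± 0.12 and 0.39 ± 0.12. The choroid plexus marker Ttr rose by 0.59 ± 0.16 in sham and was at 0.14 ± 0.16 in BCAS (adjusted p = 0.583), where the PPAR target Angptl4 rose by 0.46 ± 0.16. In sham Fkbp5 was at 0.25 ± 0.12 (adjusted p = 0.108) and Angptl4 at 0.29 ± 0.16 (adjusted p = 0.182), and in BCAS Pdk4 was at 0.17 ± 0.09 (adjusted p = 0.197). The Angptl4 call was lost without BCAS AL day 1 replicate 2 or 3 or BCAS IF day 7 replicate 2. With the clock score as a covariate none of the fasting calls of genes named in this part passed, but the score lay higher in every IF group than in every AL group and holds Per1 and Nr1d1, so this fit could not separate it from fasting. The interaction did not pass for Ttr, Angptl4, Fkbp5 or Pdk4 (adjusted p = 0.999 each). Snap25, Mbp, Gfap, Prl and Hba-a1 passed in none of the 4 comparisons of means, and Per1, Per2, Dbp, Nr1d1, Fkbp5, Pdk4, Angptl4 and Ttr did not pass with BCAS under either diet.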
